A study of Homo sapiens with 8 samples.

How the data were processed

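RNA of 8 samples of MDA-MB-231 cells, an established breast cancer cell line, was measured on 1-colour (Cy3) Agilent human 8x60k arrays, 1 array per sample, after 24 h in suspension. Per the labels' protocols, cells were detached with trypsin and kept on agar-coated dishes, and total RNA was amplified from an oligo-dT primer. Amplification from the poly(A) end favours the 3' end of transcripts, so a probe far from it loses signal where RNA is degraded.

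Per the file headers, the arrays were scanned at 3 microns per pixel and read with Agilent Feature Extraction 11.5.1.1, with spatial and multiplicative detrending on and a grid built on hg19, and all 8 arrays lay on 1 slide. The slide holds 2 rows of arrays. Suspension and shPHLPP2 occupied 1 row, shPHLPP2_LY and DDAkt the other, so a comparison between the rows also holds any difference between them. The deposited scanner files hold the processed intensity of each spot (background-subtracted, detrended, with a substitute value where a spot was not above background), the mean and local background intensity, and flags. The deposited table of the series holds 43305 gene names with log2 values. For 32087 names with a single spot its columns equalled log2 of the processed signal minus a constant per array (SD of the difference up to 0.0025), and the 75th percentile of each column was near 0, between 0.0053 and 0.0116. Its column medians were -4.47, -4.40, -4.33, -3.93, -4.18, -4.11, -4.46 and -4.37 from Suspension replicate 1 to DDAkt replicate 2. How the submitters merged several probes of a gene in that table is not given in the sources used here. It served as an alternative only.

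From the processed intensity, log2 was taken and each array's 75th percentile over its 60901 non-control spots was subtracted. Spots marked as outliers were left out, and spots of 1 probe were averaged, which gave 58201 probes. A probe was tested if it was well above background (on at least 0.5 of its spots) on both arrays of at least 1 group, which left 24405 probes with 5 missing values. Symbols came from the RefSeq gene table through the unversioned accession, which matched 31104 of the probes and 18568 of those tested, and the array's own gene name was kept otherwise. The tested probes carried 18854 names. A gene was represented by its tested probe with the highest mean over all arrays, and disagreement between probes of named genes is given where it changes the reading. Coordinates are those of the files.

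limma 3.58.1 in R 4.3.3 fitted the 4 group means over all 8 arrays (4 residual degrees of freedom, 3.07 added by moderation), with Benjamini-Hochberg adjustment per comparison and calls at an adjusted p under 0.05. Each probe had 1 spread pooled over the 4 groups. An SE can thus be too wide for groups with close replicates and too narrow for DDAkt, whose replicates lay furthest apart. The comparisons and their tests, the alternatives (but 1 named below), the 36 gene lists and the rule for named genes were fixed before the data were examined; tests of explanations chosen later are named as such where they stand. Named genes are PHLPP2, PHLPP1 and AKT genes, then among called leading probes that were well above background on both arrays of the higher group and whose 2 groups do not overlap the 8 largest rises and 8 largest falls per main comparison (4 and 4 in the 2 others), and up to 4 called members of each list that was called or held at least 3 called members. Names of forms used for noncoding, uncharacterised or clone transcripts (LINC, LOC, antisense, accession-like) and sex-linked markers were left out of that rule, which keeps a noncoding gene with a name of another form. Some genes named by that rule are not reported here. Non-overlap of 2 against 2 arrays arises by chance in 1 of 3 cases. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare them with other genes. In DDAkt against Suspension, 24 of 36 lists were not called (adjusted p from 0.0582 to 0.971), in shPHLPP2 against Suspension 28 (0.0688 to 0.985) and in LY against shPHLPP2 30 (0.160 to 0.954).

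The fit was tested on simulated data with known changes over 24405 probes, each with 1 spread for all groups. For shPHLPP2 against Suspension it recovered 6% of changes of 1 log2 unit, 72% of 2, 98% of 3 and 98% of 4. For DDAkt against Suspension the shares were 4%, 80%, 100% and 100%, and for LY against shPHLPP2 12%, 80%, 94% and 100%. These shares hold for a common spread and 50 changed probes of each size. They do not give the power for DDAkt, whose replicates lay further apart and where 4027 probes were called. The effect of shared arrays on correlations was gauged with 100 simulations of unchanged groups, each with its own group's replicate spread. Alternatives were normexp (offset 50) on the mean and background intensities, quantile normalization, scaling to the median, the deposited table, no filter, a filter on all arrays, a fit of the 2 groups alone, the replicate number as a block, trended and robust moderation, 1 probe per gene, outlier spots kept, and each array left out in turn, where a lone array is assumed to vary like the other groups. A fit without the DDAkt arrays was added after seeing the data. Intervals of medians are 95% bootstrap intervals from 1000 draws. Figures were drawn with matplotlib 3.10.9 in Python.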

Results

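Gene expression was measured in MDA-MB-231 cells, a human triple-negative breast cancer line of mesenchymal character, kept in suspension for 24 h on agar-coated dishes. The 8 samples fell into 4 groups of 2: plain suspension culture (Suspension), cells stable for a hairpin against PHLPP2 (shPHLPP2), the same hairpin cells treated with a compound that the labels call LY (shPHLPP2_LY), and cells stable for a GFP- and HA-tagged Akt with the substitutions T308D and S473D (DDAkt). PHLPP2 is a phosphatase that removes an activating phosphate from AKT kinases, and aspartates at those 2 residues mimic the phosphorylated, active kinase. The design therefore asks what loss of the phosphatase, an AKT mimic, and LY on top of the hairpin do to transcripts of cells without matrix attachment. Each sample was hybridised to 1 array with 1 colour. Between 38.3% and 43.0% of the 58201 probes were well above background per array, the 75th percentile of the processed signal lay between 67.9 and 109 units, and no spot was saturated. The labels do not say that the 2 replicates of a group were separate cultures, so the p-values measure only the spread between these samples, and the number of arrays limits the precision. Of the probes, 24405 were well above background on both arrays of at least 1 group and were tested. Levels are log2 signal minus the array's 75th percentile, given as mean ± SD with n = 2 arrays. Fold changes are log2 differences from limma with their standard error (SE) and the adjusted p. Where a probe was not well above background on either array of the lower group, the fold is a lower bound, set against the lowest signal that was well above background.

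The DDAkt arrays stood apart from the other 6, replicate 1 more so than replicate 2. Across tested probes, which are not independent replicates, the 2 arrays of a group correlated at 0.985 to 0.994 in the other 3 groups and at 0.962 in DDAkt. Pairs of 1 DDAkt array with an array of another group correlated at 0.902 to 0.970. DDAkt replicate 2 correlated more closely with each Suspension array (0.970) than with DDAkt replicate 1 (0.962). The SD of the difference between replicates was 0.36 in Suspension, 0.42 in shPHLPP2, 0.55 in shPHLPP2_LY and 0.84 in DDAkt, where 19.3% of probes were over 2-fold apart. In DDAkt against Suspension the 5'-most probe of a transcript was lower than its 3'-most probe by a median log2 difference of -0.20 over 2105 transcripts (95% bootstrap interval -0.22 to -0.17), against 0.029 in shPHLPP2 against Suspension. With this scaling the median change of all tested probes was -0.20 in DDAkt against Suspension and -0.029 in shPHLPP2 against Suspension.

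**Figure D1:**
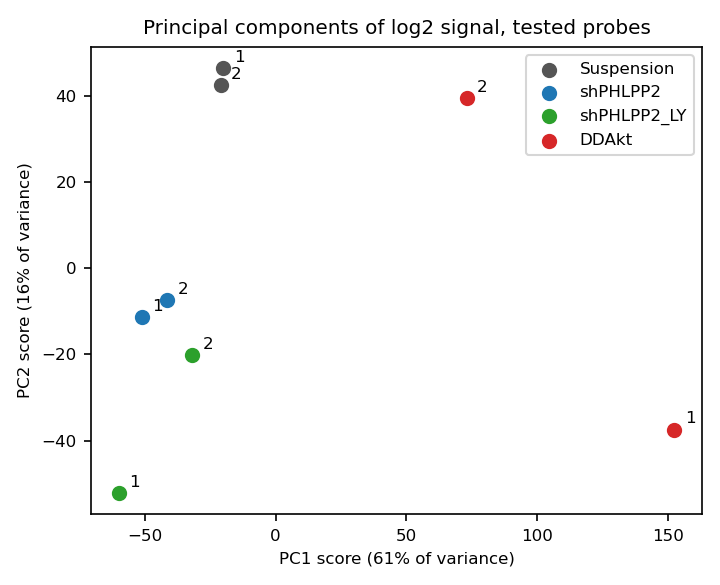
Principal component scores of the 8 arrays over the tested probes, with PC1 on the horizontal and PC2 on the vertical axis (scores without unit); points are arrays, coloured by group and numbered by replicate. DDAkt replicate 1 lies at 152 and replicate 2 at 73.1 on PC1, and the other 6 arrays lie between -60.0 and -20.0. On PC2, DDAkt replicate 2 lies at 39.5, near the Suspension arrays at 46.4 and 42.5, and DDAkt replicate 1 at -37.5.

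PHLPP2 transcript was lower in the hairpin cells, by a difference that did not pass the adjusted threshold. Its tested probe lies on chromosome 16 from 71679160 to 71679219 (hg19), at nucleotide 7924 of the PHLPP2 transcript. Another PHLPP2 probe, at nucleotide 3277, did not pass the background filter and was not tested. At the tested probe the level was 1.69 ± 0.04 in Suspension and 0.57 ± 0.15 in shPHLPP2, and both hairpin arrays lay below both plain arrays. The log2 change was -1.12 (SE 0.38, limma adjusted p = 0.589, unadjusted p = 0.0216). With LY the level was 0.35 ± 0.12, a log2 change of -1.34 against Suspension (SE 0.38, limma adjusted p = 0.227, unadjusted p = 0.00962). In a fit without the DDAkt arrays, an alternative chosen after seeing the data, the adjusted p of this PHLPP2 change with LY was 0.0341, while that of the hairpin alone was 0.0772 and did not pass. Over all alternatives the adjusted p with LY ranged from 0.0341 to 0.792, and from the deposited table the change was -2.20. The DDAkt arrays gave PHLPP2 levels of -0.065 and 1.17, and their mean change of -1.14 did not pass either (SE 0.38, adjusted p = 0.0754). Their SD of 0.87 enters the pooled SE of every PHLPP2 comparison in the main fit. The adjusted p of the hairpin there thus reflects the DDAkt spread as well as that of the compared arrays. PHLPP1, the related phosphatase, differed from Suspension by 0.18 in shPHLPP2 (SE 0.29, adjusted p = 0.977).

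The AKT1 probe did not differ in the DDAkt cells. It lies on chromosome 14 from 105235975 to 105236034 (hg19), at nucleotide 2640 of the transcript. AKT1 stood at 2.86 ± 0.05 in Suspension and 2.73 ± 0.26 in DDAkt, a log2 change of -0.13 (SE 0.24, adjusted p = 0.693). The labels name neither the AKT gene of the transgene nor its sequence, so whether a probe lies within it is open. A probe outside the transgene cannot read it, so the AKT1 value is no check of its expression. The leading probe of AKT2 differed by 0.10 (SE 0.22, adjusted p = 0.752). Another AKT2 probe, at nucleotide 516 of its transcript, on chromosome 19 from 40761075 to 40761134, rose by 2.17 (SE 0.38, adjusted p = 0.0238). It was singled out after its values were seen. The leading AKT2 probe lies at nucleotide 2761, and the remaining one, at nucleotide 5240, changed by 0.39 (SE 0.28, limma adjusted p = 0.323). The 3 AKT2 probes thus disagree in the size of the change.

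**Figure D2:**
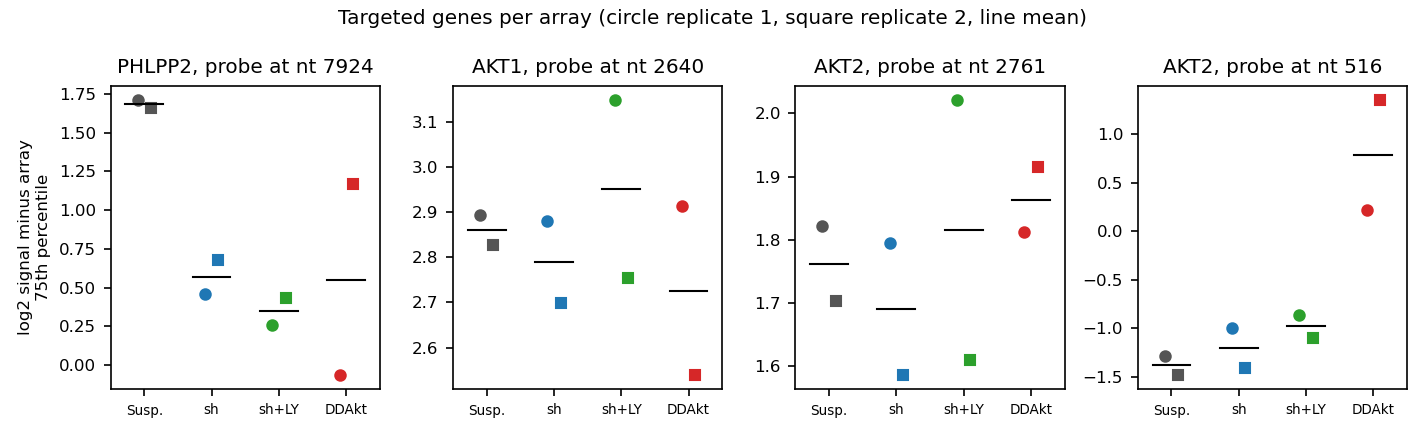
Log2 signal minus the array's 75th percentile (vertical axis) of the PHLPP2, AKT1 and 2 AKT2 probes in each array of the 4 groups (horizontal axis; sh is shPHLPP2, sh+LY is shPHLPP2_LY); circles are replicate 1, squares replicate 2 and lines group means. PHLPP2 falls from 1.69 in Suspension to 0.57 in shPHLPP2, and the 2 DDAkt arrays lie at -0.065 and 1.17.

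Few probes passed the threshold in hairpin cells against plain suspension cells, and most of those rose from a level that was below background. The smallest called change was 1.80 log2 units, and the fit recovered 6% of simulated changes of 1 unit. Smaller changes may thus have been missed. CDH18, a cadherin, rose at least 53.7-fold, SPOCK1, a secreted proteoglycan, at least 27.0-fold, and SSX1, a cancer-testis antigen, at least 19.5-fold. COX7B2, a testis form of a cytochrome c oxidase subunit, was well above background in both groups and rose by 6.14 on the log2 scale (SE 0.28, adjusted p = 0.000338), from -2.42 ± 0.12 to 3.72 ± 0.07. The chemokine CCL2 rose by 4.04 (SE 0.29, adjusted p = 0.00228). The interferon-induced gene IFIT1 fell by 1.83 on the log2 scale (SE 0.25, adjusted p = 0.0458), and FGF13, of the fibroblast growth factor family, fell by 1.80 (SE 0.24, adjusted p = 0.0454).

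In all, limma called 80 of 24405 probes at an adjusted p under 0.05, 65 higher and 15 lower, and 1692 had an unadjusted p under 0.05. Of the 65 higher probes, 44 were not well above background on either Suspension array. The zinc finger gene ZNF300 rose at least 8.55-fold, NAP1L5 at least 8.87-fold and SSX4B at least 19.7-fold, while RFPL4AL1 rose by 5.09 (SE 0.53, adjusted p = 0.0139). SSX genes are near-identical copies, so their probes may read more than 1 of them. Among the falls, the cancer-testis antigen CTAG1A changed by -2.21 (SE 0.20, adjusted p = 0.00675), CH25H, which makes 25-hydroxycholesterol, by -1.98 (SE 0.26, adjusted p = 0.0388), and CCNYL4 by -2.38 (SE 0.22, adjusted p = 0.00675). PKD1L2, the long noncoding PCGEM1 and MAGEC2 fell to below background, by at least 1.91-fold, 1.81-fold and 1.53-fold.

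Of 36 gene lists, camera called 8 with a preset correlation, 7 lower and 1 higher. With an estimated correlation it called none, at adjusted p = 0.738 for the NF-kB list and the leukocyte markers and adjusted p = 0.862 for the other 6, and fry called none. Interferon response genes had a median log2 change of -0.23 (adjusted p = 0.00502, and adjusted p = 0.862 with an estimated correlation), and 1 of 39 fell, IFIT1. Antigen presentation genes had a median of -0.22 (adjusted p = 0.00676, and adjusted p = 0.862 with an estimated correlation) and no called member of 26. NF-kB targets, cytokines and chemokines had a median of -0.45 (adjusted p = 0.0110, and adjusted p = 0.738 with an estimated correlation), although the 1 called member of 43, CCL2, rose. G1/S and DNA replication genes (median -0.19, adjusted p = 0.0103), G2/M and mitosis genes (-0.16, adjusted p = 0.0229), NRF2 targets of the oxidative stress response (-0.23, adjusted p = 0.0112) and ribosome biogenesis and MYC targets (-0.19, adjusted p = 0.0413) had no called member, each at adjusted p = 0.862 with an estimated correlation. G2/M and mitosis genes stood at 0.022 without shPHLPP2 replicate 1. Leukocyte markers, of which 6 could be tested, had a median of 0.41 (adjusted p = 0.0241, and adjusted p = 0.738 with an estimated correlation) and no called member either. Among 13 luminal and other breast epithelial markers, FOXA1 was called, at 3.19 (SE 0.44, adjusted p = 0.0487), and was singled out after its value was seen. Adjusted over the list alone, 3 interferon genes fell, and 1 of the NF-kB list rose and 1 fell. Without shPHLPP2 replicate 2, 5 lists were called. The preset calls of interferon response and antigen presentation held under all alternatives, and the other 6 were each lost under at least 1, 5 of them with an array left out. The number of called probes was 26 after normexp background correction, 44 without a filter on dim probes and 9 among probes well above background on all 8 arrays. It was 30 without Suspension replicate 1, 39 without Suspension replicate 2, 46 without shPHLPP2 replicate 1 and 41 without shPHLPP2 replicate 2. With scaling to the median, which moved the median change of all tested probes from -0.029 to -0.31, 70.3% of calls were higher in place of 81.3%.

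In the main fit DDAkt cells differed from plain suspension cells in more probes than hairpin cells did, with PHGDH and HSPA1A among the lower genes and CSF1 among the higher, but the order of the counts turned when either Suspension array was left out. PHGDH, the first enzyme of serine synthesis, fell from 1.54 ± 0.08 to -2.22 ± 0.42, a change of -3.75 (SE 0.27, adjusted p = 0.00539). HSPA1A, an inducible HSP70 chaperone, fell from 8.76 ± 0.04 to 4.70 ± 1.02, a change of -4.06 (SE 0.62, adjusted p = 0.0202). CSF1, the macrophage growth factor, rose from 0.43 ± 0.10 to 3.24 ± 0.30, a change of 2.81 (SE 0.22, adjusted p = 0.00607), and CXCL10, an interferon-induced chemokine, rose at least 19.7-fold, and its DDAkt arrays had an SD of 2.66. RAB17, a GTPase of epithelial trafficking, rose at least 38.9-fold, and TIMP3, an inhibitor of metalloproteases, rose by 2.96 (SE 0.24, adjusted p = 0.00607). These DDAkt changes were measured on arrays that also differed from Suspension by slide row and by the lower signal of 5' probes given above.

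Targets of ATF4, the transcription factor of the amino acid stress response, were the list with the lowest median, -1.41 (adjusted p = 1.18e-05, and adjusted p = 0.872 with an estimated correlation): 18 of 34 fell and 1 rose. Beside PHGDH these included PPP1R15A at -3.54 (SE 0.64, adjusted p = 0.0246; SD of the DDAkt arrays 1.32), the mTORC1 inhibitor SESN2 at -3.33 (SE 0.59, adjusted p = 0.0240; SD 1.26) and NUPR1 at -3.23 (SE 0.33, adjusted p = 0.0103). Of 25 heat shock proteins, 9 fell and none rose (median -1.26, adjusted p = 3.04e-05, and adjusted p = 0.872 with an estimated correlation), with HSPA1B at -2.82 (SE 0.48, adjusted p = 0.0236; SD 0.96). HSPA1A and HSPA1B are near-identical copies and their probes may share signal. HSPA6, another heat-inducible HSP70, changed by -5.20 (SE 1.29, adjusted p = 0.0415), and its DDAkt arrays had an SD of 3.02. Immediate early and AP-1 genes had 11 of 35 lower and 2 higher (median -1.003, adjusted p = 0.00880, and adjusted p = 0.872 with an estimated correlation). They included FOSB at -5.21 (SE 1.05, adjusted p = 0.0293; SD of the DDAkt arrays 2.46), FOS at -4.18 (SE 0.82, adjusted p = 0.0282; SD 1.65) and CCN1 at -2.65 (SE 0.57, adjusted p = 0.0321; SD 1.41). Of 25 YAP/TEAD targets, 9 fell and none rose (median -0.59, adjusted p = 0.00584, and adjusted p = 0.872 with an estimated correlation), among them CCN2 at -3.20 (SE 0.43, adjusted p = 0.0154; SD 0.89) and AMOTL2 at -3.04 (SE 0.39, adjusted p = 0.0145).

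Ribosome biogenesis and MYC targets fell in 11 of 41 genes with none higher (median -1.12, adjusted p = 1.09e-06, and adjusted p = 0.872 with an estimated correlation), with MYC itself at -1.62 (SE 0.32, adjusted p = 0.0289) and MRTO4 at -2.48 (SE 0.42, adjusted p = 0.0232; SD of the DDAkt arrays 0.98). Ribosomal proteins had a median of -0.68 (adjusted p = 8.92e-07, and adjusted p = 0.872 with an estimated correlation) with 3 of 49 lower, among them RPS3 at -1.22 (SE 0.20, adjusted p = 0.0229). G2/M and mitosis genes had a median of -0.49 (adjusted p = 0.0140, and adjusted p = 0.904 with an estimated correlation) and 5 of 47 lower, including AURKB at -1.25 (SE 0.30, adjusted p = 0.0392). The mitochondrial respiratory chain had a median of -0.36 (adjusted p = 0.0258, and adjusted p = 0.904 with an estimated correlation) and 1 of 45 lower, NDUFC2, but its direction turned with quantile normalization (median 0.23) and its call was lost in 3 of 4 fits with an array left out. SNAI1, a transcription factor of the mesenchymal state, changed by -4.64 (SE 1.20, adjusted p = 0.0447), and its DDAkt arrays, at -1.14 and 3.05, had an SD of 2.96. The largest named fall was that of SPANXA1, a cancer-testis gene, at -6.40 (SE 0.30, adjusted p = 0.00159). SPANXB1 and SPANXC, near-identical relatives, changed by -4.93 and -5.19 (SD of the DDAkt arrays 0.94 and 1.27).

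NF-kB targets, cytokines and chemokines had 8 of 43 higher and 1 lower (median 0.52, adjusted p = 0.00268, and adjusted p = 0.872 with an estimated correlation), with CSF3 at 3.23 (SE 0.51, adjusted p = 0.0216) and CXCL1 at 2.62 (SE 0.43, adjusted p = 0.0227; SD of the DDAkt arrays 0.96) beside CSF1 and CXCL10. Markers of other cell types were higher on the same arrays in 2 of 6 leukocyte genes (median -0.010, adjusted p = 0.465), 1 of 13 luminal and other breast epithelial genes (median 0.099, adjusted p = 0.465) and 2 of 4 endothelial and fibroblast genes (median 1.15, too few for a list test), and none was lower. Interferon response genes had a median of 0.31 (adjusted p = 0.00191, and adjusted p = 0.872 with an estimated correlation) with 2 of 39 higher: GBP2 at 2.53 (SE 0.61, adjusted p = 0.0394; SD of the DDAkt arrays 1.43) and XAF1, which rose at least 2.67-fold. Extracellular matrix genes had a median of 0.45 (adjusted p = 0.0273, and adjusted p = 0.872 with an estimated correlation) but went both ways, 6 of 38 higher and 6 lower. COL6A1, a collagen, rose by 1.79 (SE 0.38, adjusted p = 0.0320), while THBS1, thrombospondin 1, fell by 1.95 (SE 0.36, adjusted p = 0.0249). Fatty acid synthesis genes had 3 of 18 higher and none lower (median 0.24, adjusted p = 0.0450, and adjusted p = 0.872 with an estimated correlation), including ACACB at 1.21 (SE 0.27, adjusted p = 0.0346). ELF3, an epithelial transcription factor, rose at least 11.9-fold, and LFNG, which modifies Notch receptors, rose by 4.64 (SE 0.92, adjusted p = 0.0286; SD 1.68) at one probe and 1.31 (adjusted p = 0.113) at its other.

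Limma called 4027 probes, 1545 higher and 2482 lower, and 9710 had an unadjusted p under 0.05. With quantile normalization, where the median change of all tested probes was -0.065, 47.7% of calls were higher in place of 38.4%. Adjusted over the list alone, 26 ATF4 targets fell and 2 rose, 18 heat shock proteins fell, and 12 genes of the NF-kB list rose and 2 fell. Of the 12 preset list calls, those of ATF4 targets, heat shock proteins, immediate early genes, YAP/TEAD targets, ribosome biogenesis and the NF-kB list held under all alternatives. Without DDAkt replicate 1 the interferon response (adjusted p = 0.193), extracellular matrix (adjusted p = 0.290), fatty acid synthesis (adjusted p = 0.171) and G2/M lists (adjusted p = 0.478) were lost, and with quantile normalization the ribosomal proteins (adjusted p = 0.346). Camera with an estimated correlation called none of the 12 lists that it called with the preset correlation, and fry called none either (lowest adjusted p = 0.0546). The count moved with the fit more than the changes did. Without Suspension replicate 1 or 2 the median change of all tested probes stayed at -0.20, yet fewer probes passed than with the hairpin. A group of 1 array leaves fewer degrees of freedom, whichever array is left out. Without a DDAkt array, the spread between the DDAkt replicates also drops out of the pooled SE. Without a Suspension array that spread stays. Why the counts moved was not tested. More probes passed without DDAkt replicate 2 than in the main fit, and fewer without DDAkt replicate 1. The count was 0 when only the 2 groups were fitted and 42 without a filter on dim probes, where the hairpin had 125 and 44. From the deposited table of gene values it was 2229.

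**Figure D3:**
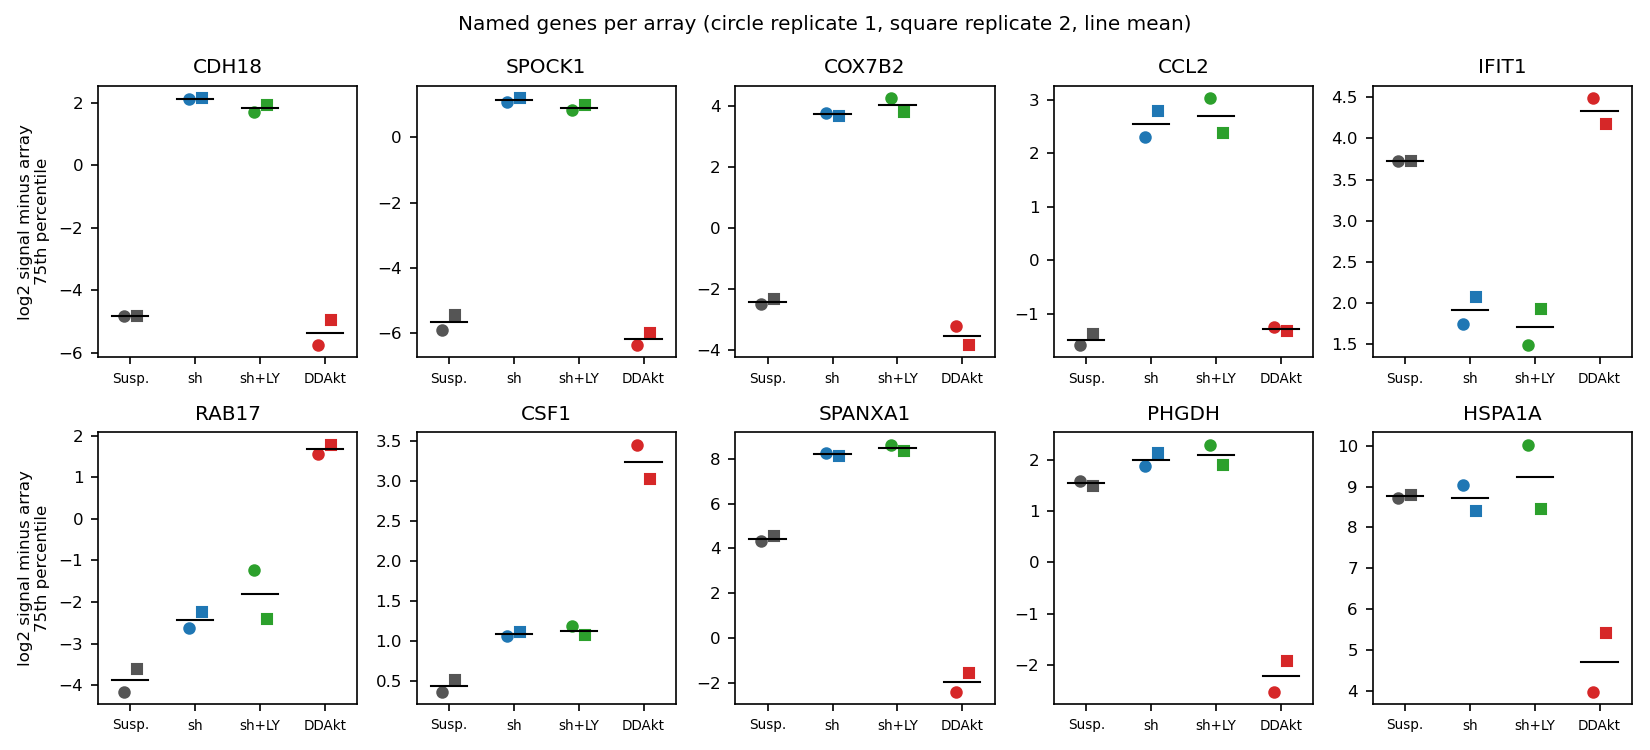
Log2 signal minus the array's 75th percentile (vertical axis) of 10 named genes in each array of the 4 groups (horizontal axis; sh is shPHLPP2, sh+LY is shPHLPP2_LY); circles are replicate 1, squares replicate 2 and lines group means. CDH18 lies at 2.14 in shPHLPP2 and -4.82 in Suspension, and HSPA1A at 8.76 in Suspension and 4.70 in DDAkt.

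Between hairpin cells with and without LY, 8 probes were called, all of them higher with LY and all below background on both shPHLPP2 arrays. The 2 groups lay in different slide rows. For these probes and for the lists below, an effect of LY thus cannot be told apart from a row difference. PADI6, an arginine deiminase known from oocytes, rose at least 5.02-fold, and PBOV1 at least 1.65-fold. Of the 8 probes, 5 belong to long noncoding or uncharacterised transcripts. Limma found 811 probes at an unadjusted p under 0.05. Without shPHLPP2 replicate 1 it called 6, of which 33.3% were higher and 2 were among the 8. It called 3 without shPHLPP2 replicate 2, of which 66.7% were higher, 4 without shPHLPP2_LY replicate 1 and 3 without shPHLPP2_LY replicate 2. It called 13 with scaling to the median (76.9% higher), 9 with quantile normalization (88.9% higher) and 25 from the deposited table (72.0% higher), and 0 after normexp, with trended and robust moderation, among probes above background on all arrays, or when only the 2 groups were fitted.

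Among the gene lists, camera called 6 with the preset correlation and 3 without shPHLPP2 replicate 2, although no member of any passed its own test over all genes or over the list alone. Ribosome biogenesis and MYC targets had a median of -0.38 (41 genes, adjusted p = 1.24e-08) and replication-dependent histones of 0.33 (35 genes, adjusted p = 3.47e-08), both at adjusted p = 0.950 with an estimated correlation. Histone genes are many near-identical copies, so their probes are not separate evidence. Amplification from an oligo-dT primer reads transcripts with a poly(A) tail, so these values may not give the level of histone transcripts that lack one. Smaller shifts were called in ribosomal proteins (0.17, adjusted p = 0.00168), the mitochondrial respiratory chain (0.15, adjusted p = 0.00748), lysosome genes (0.16, adjusted p = 0.0355) and G1/S and DNA replication genes (-0.096, adjusted p = 0.0400), each at adjusted p = 0.950 with an estimated correlation. With quantile normalization the ribosomal proteins turned to -0.034, and without shPHLPP2_LY replicate 1 they stood at -0.00163 and the respiratory chain at -0.032. The preset calls of ribosome biogenesis and of the histones held under all alternatives; those of lysosome and of G1/S genes were lost in 3 of 4 fits with an array left out, and those of ribosomal proteins and the respiratory chain in 2 of 4. In fry the adjusted p was 0.990 for each of the 6 lists.

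**Figure D4:**
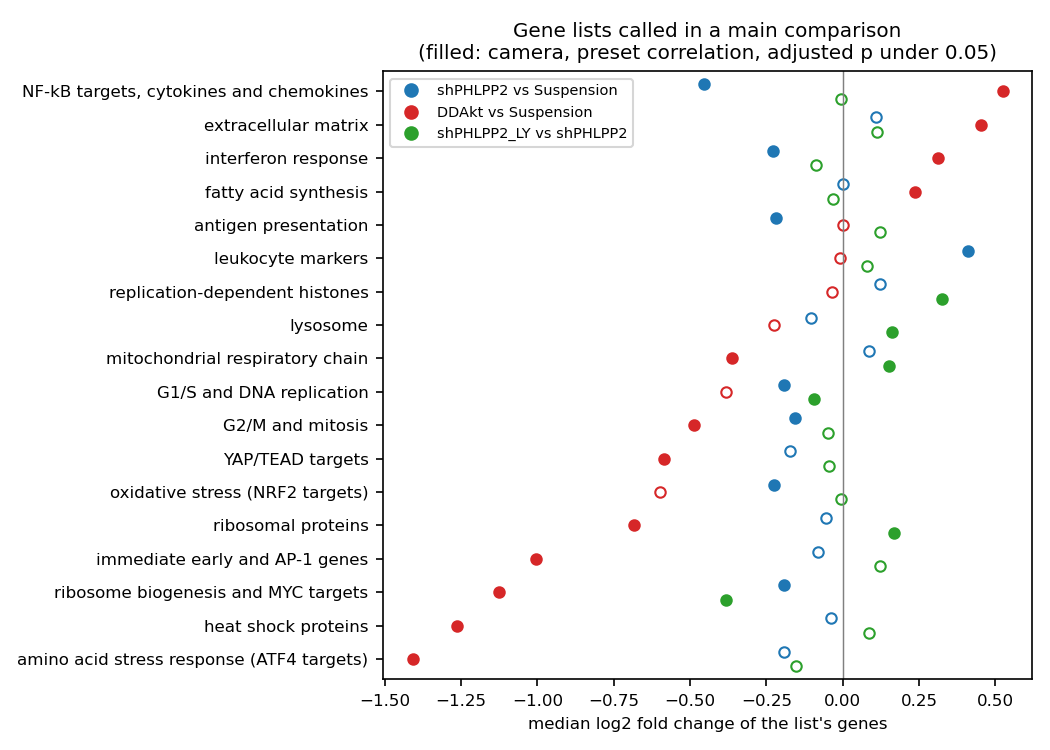
Median log2 fold change (horizontal axis) of each gene list called in at least 1 main comparison (vertical axis), in shPHLPP2 against Suspension, DDAkt against Suspension and LY against shPHLPP2; filled points passed camera with the preset correlation and open points did not. ATF4 targets lie lowest in DDAkt at -1.41, and the NF-kB list lies at 0.52 in DDAkt and -0.45 in shPHLPP2; the respiratory chain turns sign in DDAkt with quantile normalization, and the ribosomal proteins do so with LY.

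Most probes called with the hairpin were also called in hairpin cells with LY against the same Suspension arrays. That comparison crosses the slide rows too. Against Suspension, the hairpin cells with LY had 126 called probes, 92 higher and 34 lower, with 3468 at an unadjusted p under 0.05. The count was 37 without Suspension replicate 1, 48 without Suspension replicate 2, 48 without shPHLPP2_LY replicate 1 and 77 without shPHLPP2_LY replicate 2, and with scaling to the median 206, of which 50% were higher in place of 73.0%. CDH18 rose at least 43.3-fold, SPOCK1 at least 22.9-fold and SSX1 at least 22.1-fold, and COX7B2 rose by 6.44 (SE 0.28, adjusted p = 0.000298). The cytokine IL1A changed by -2.67 (SE 0.26, adjusted p = 0.00860). Of the 65 probes that rose in shPHLPP2, 53 were called higher with LY too, and of the 15 that fell, 12 were called lower. Lists of these sizes drawn independently would share 0.245 and 0.0209, but part of the excess may come from the shared Suspension arrays. Simulated unchanged groups against those arrays shared 0, but groups without change have few calls to share. That 0 was nearly fixed beforehand and gives no benchmark for groups that differ. The count of the 2 directions together, 65, was 25 and 33 without Suspension replicate 1 and 2, 37 and 33 without shPHLPP2 replicate 1 and 2, and 37 without shPHLPP2_LY replicate 1. Limma called 0 of the 80 hairpin probes the opposite way in LY against shPHLPP2 (811 probes of that comparison had an unadjusted p under 0.05), but 9 from the deposited table, 3 with scaling to the median, 1 with quantile normalization, 4 without shPHLPP2 replicate 1 and 1 without shPHLPP2 replicate 2. Across 18854 genes, which are not independent replicates, the correlation of the hairpin's log2 changes with those of LY against shPHLPP2 was -0.0955, where simulated unchanged groups that share the shPHLPP2 arrays gave -0.465. The covariance was -0.0182 against -0.0446 in the simulation, a difference of 0.0264. This correlation changed sign with normexp (0.123), among probes above background on all arrays (0.103) and without shPHLPP2_LY replicate 2 (0.0219).

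Few of the probes called with the hairpin were called the same way with the AKT mimic. Of the 80 probes called with the hairpin, 10 were called the same way in DDAkt, 3 higher and 7 lower, and 19 the opposite way. Lists of these sizes drawn independently would share 4.11 higher and 1.53 lower. Simulated unchanged groups against the shared Suspension arrays shared 0, which, as above, was nearly fixed beforehand and gives no benchmark. The 19 were 18 that rose with the hairpin and 1 that fell, where independent lists would give 6.61 and 0.950. The simulation gave 0, with the same limit. Of the 18, 6 were below background on both Suspension arrays. The 3 higher were CD33, SCIRT and an uncharacterised transcript, named after their values were seen. FGF13 and CTAG1A fell in both, with DDAkt changes of -1.97 and -4.21. The count of 10 was 0 without either Suspension array, 5 and 4 without shPHLPP2 replicate 1 and 2, and 16 and 22 without DDAkt replicate 1 and 2. That of 19 was 0 without either Suspension array, 4 and 5 without shPHLPP2 replicate 1 and 2, and 33 without DDAkt replicate 2. Across genes the log2 changes correlated at 0.0246, against 0.253 in simulated unchanged groups, and the covariance was 0.0115 against 0.0321, a difference of -0.0207. The correlation was -0.0160 with quantile normalization, -0.0398 without shPHLPP2 replicate 2 and -0.00281 without DDAkt replicate 1. The controls were not split, since that would leave 1 Suspension array to each comparison, so part of any overlap may come from sharing them.

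Compared directly, DDAkt and shPHLPP2 cells differed in 5992 probes, 2387 higher and 3605 lower in DDAkt, with 10637 at an unadjusted p under 0.05. SPANXA1 was lower in DDAkt (log2 change -10.16, SE 0.30, adjusted p = 7.44e-05), and RFPL4AL1 changed by -7.93 (SE 0.53, adjusted p = 0.00102), with 1 of the 2 DDAkt arrays above background and an SD of 1.25 between them. RIPOR3 was higher by 7.87 (SE 0.78, adjusted p = 0.00343), with 1 of the 2 shPHLPP2 arrays above background and an SD of 1.85 between them, so the size is uncertain. CSF3 was higher by 5.10 (SE 0.51, adjusted p = 0.00359). Interferon response genes had 11 of 39 higher and none lower (median 0.56, adjusted p = 1.66e-05, and adjusted p = 0.781 with an estimated correlation), and the NF-kB list 14 of 43 higher and 3 lower (median 0.64, adjusted p = 6.54e-05). The NF-kB list was also called by fry (adjusted p = 0.0151), but not with an estimated correlation (adjusted p = 0.370). Antigen presentation genes had 3 of 26 higher (median 0.35, adjusted p = 0.0119). Lower were heat shock proteins (10 of 25, median -1.46, adjusted p = 6.54e-05), ATF4 targets (15 of 34, 3 higher, median -1.16, adjusted p = 0.000722), ribosome biogenesis (8 of 41, median -0.92, adjusted p = 0.000225), ribosomal proteins (11 of 49, median -0.59, adjusted p = 1.66e-05) and the respiratory chain (5 of 45, median -0.45, adjusted p = 0.00399). These 6 each had adjusted p = 0.827 with an estimated correlation. With quantile normalization the respiratory chain turned to 0.042 and the ribosomal proteins lost their call (median -0.013), and antigen presentation lost its call without DDAkt replicate 1 (adjusted p = 0.614). These 2 groups lay in different slide rows, and the 5' minus 3' difference was -0.23 (95% bootstrap interval -0.25 to -0.21). The count was 321 without shPHLPP2 replicate 1, 533 without shPHLPP2 replicate 2, 3964 without DDAkt replicate 1, 11760 without DDAkt replicate 2 and 409 when only the 2 groups were fitted. Of the calls, 50.3% were higher with quantile normalization and 65.9% with scaling to the median, in place of 39.8%.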

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

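The direction of PHLPP2 against Suspension held in shPHLPP2 and in shPHLPP2_LY under each alternative run, with log2 changes from -1.23 to -1.01 and from -1.43 to -1.25 when 1 array was left out. Over the other settings it ranged from -1.40 (median scaling) to -0.82 (normexp) in shPHLPP2 and from -2.20 (deposited table) to -0.93 (normexp) with LY. Its adjusted p with LY passed without the DDAkt arrays (change -1.34, SE 0.15, adjusted p = 0.0341), an alternative chosen after seeing the data, and that in shPHLPP2 did not (adjusted p = 0.0772). AKT1 in DDAkt turned to 0.069 with normexp and 0.13 with quantile normalization, and ranged from -0.32 to 0.053 with 1 array left out. Apart from these 3 results, named genes gave 1663 values with direction and side of the threshold kept, 669 weaker, 5 stronger and 25 that turned, the last all of PHLPP and AKT genes that did not pass. Signal over background limits the genes that rose from below background, whose fold is only a lower bound. Among probes well above background on all 8 arrays, limma called 9 in shPHLPP2 against Suspension. That filter removes probes below background in Suspension by definition, so the count does not test their rises.

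In shPHLPP2 against Suspension the called probes numbered 26 with normexp, 44 without a filter, 9 with the filter on all arrays, 125 with 2 groups in the fit and 30 to 46 with 1 array left out. Lists called were 5 with median scaling, 13 with 2 groups and 5 to 9 with 1 array left out. In DDAkt against Suspension the counts were 2229 from the deposited table, 42 without a filter, 0 with 2 groups and 0 to 11238 with 1 array left out, and 10 to 15 lists. With the replicate number as a block, DDAkt against Suspension gave 2430, though the labels name no pairing of the samples; the replicate differences correlated at 0.248 between shPHLPP2 and shPHLPP2_LY and at -0.0151 to 0.103 between the other groups. In DDAkt against shPHLPP2 they were 3730 from the deposited table, 1276 without a filter, 409 with 2 groups and 321 to 11760. In LY against shPHLPP2 they were 0 with normexp, the filter on all arrays, 2 groups, and trended and robust moderation, 13 with median scaling, 25 from the deposited table, 2 without a filter, 3 without the DDAkt arrays and 3 to 6 with 1 array left out. Its lists were 2 with quantile normalization, 3 with median scaling, 2 from the deposited table and 3 to 7. In shPHLPP2_LY against Suspension the counts were 31 with normexp, 206 with median scaling, 56 without a filter, 9 with the filter on all arrays, 68 with trended and robust moderation, 274 without the DDAkt arrays and 37 to 77. Fewer or more probes tested account in part for the filters' counts. For the others the cause was not tested.

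The correlation of the hairpin's changes with those of LY was 0.123 with normexp, 0.103 with the filter on all arrays, -0.219 from the deposited table, -0.426 without a filter and -0.286 to 0.0219 with 1 array left out. That of the hairpin with DDAkt was -0.0482 with normexp, -0.0160 with quantile normalization, 0.0852 from the deposited table, 0.178 without a filter and -0.0398 to 0.0955. Probes called the same way in DDAkt numbered 3 with normexp, 4 without a filter, 1 with the filter on all arrays, 0 with 2 groups, 3 with trended and robust moderation and 0 to 22. Probes that LY moved the opposite way numbered 1 with quantile normalization, 3 with median scaling, 9 from the deposited table and 0 to 4. Probes called the opposite way in DDAkt numbered 11 with normexp, 2 without a filter, 4 with the filter on all arrays, 0 with 2 groups, 12 with the replicate block and 0 to 33 with 1 array left out, and those called the same way with LY 23, 39 and 8 with normexp, no filter and the filter on all arrays, 102 without the DDAkt arrays and 25 to 42. The cause was not tested.

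Among named genes that did not pass in the main fit and so have no called direction there, normexp turned PHLPP1 in shPHLPP2_LY against Suspension to 0.086 and in LY against shPHLPP2 to 0.00494, and in DDAkt against shPHLPP2 AKT1 to 0.12 and PHLPP2 to 0.089. Quantile normalization turned AKT1 to 0.00194 in shPHLPP2 against Suspension and 0.12 in DDAkt against shPHLPP2. Median scaling turned PHLPP1 in shPHLPP2 against Suspension to -0.098, AKT1 and AKT2 in shPHLPP2_LY against Suspension to -0.23 and -0.26, and AKT1 and PHLPP2 in DDAkt against shPHLPP2 to 0.15 and 0.19. With 1 array left out, DDAkt against shPHLPP2 ranged from -0.25 to 0.12 for AKT1 and -0.63 to 0.60 for PHLPP2, whose lowest value passed (adjusted p = 0.0376, without DDAkt replicate 2). In shPHLPP2 against Suspension AKT1 ranged from -0.16 to 0.019 and AKT2 from -0.18 to 0.032. In shPHLPP2_LY against Suspension AKT1 ranged from -0.11 to 0.29, AKT2 from -0.15 to 0.26 and PHLPP1 from -0.45 to 0.37. In LY against shPHLPP2 AKT1 ranged from -0.035 to 0.36, AKT2 from -0.080 to 0.33 and PHLPP1 from -0.63 to 0.19. The median of the respiratory chain in DDAkt turned with quantile normalization to 0.23 against Suspension and 0.042 against shPHLPP2, and with LY it ranged from -0.032 to 0.35. That of the ribosomal proteins with LY turned to -0.034 with quantile normalization and ranged from -0.00163 to 0.32. The G2/M and mitosis list with the hairpin ranged from -0.35 to 0.022. Without a filter the test of the lysosome list with LY turned while its median stayed at 0.15. The cause was not tested.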

Other observations

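Several lists that were not called in DDAkt against Suspension held called members. Of 30 epithelial genes, 6 rose and 3 fell, with the junction protein JUP at 2.52 (SE 0.46, adjusted p = 0.0245; SD of the DDAkt arrays 1.04), CLDN3, a tight junction claudin, at 1.70 (SE 0.24, adjusted p = 0.0178), and KRT17, a keratin, lower by at least 1.44-fold. Of 24 cholesterol synthesis genes 3 fell, among them HMGCS1 at -1.16 (SE 0.20, adjusted p = 0.0238). Of 28 NRF2 targets 4 fell, among them the thioredoxin reductase TXNRD1 at -2.71 (SE 0.45, adjusted p = 0.0229; SD 1.06). Of 36 autophagy genes 7 fell and 1 rose, with MAP1LC3B at -1.43 (SE 0.39, adjusted p = 0.0485; SD 0.85) and ATG16L2 at 2.36 (SE 0.25, adjusted p = 0.0104). Of 37 apoptosis regulators 1 rose and 3 fell: TNFSF10, which encodes the death ligand TRAIL, rose by 3.11 (SE 0.54, adjusted p = 0.0238; SD 0.92), and among the falls the survival gene MCL1 changed by -2.06 (SE 0.47, adjusted p = 0.0355; SD 1.06). Camera with the preset correlation gave these lists adjusted p from 0.114 to 0.971.

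The tests of the LY effect, of other cell types, of line differences and of a share of unchanged cells were chosen only after the result was seen; those of degraded RNA and of the slide row were set before it.

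The 65 probes that rose in shPHLPP2 could follow from the knockdown, from other cells in the cultures, or from a difference between separately derived lines. Their median log2 change with LY was -0.109 (95% bootstrap interval -0.24 to -0.0056). Whether LY blocked its target in these cells was not measured, so this value cannot decide whether LY-sensitive signalling kept the probes high. At most 1 marker of any of the 3 lists of other cell types was called higher (FOXA1), but markers that missed the threshold exclude nothing. Of the risen probes 67.7% were below background on both Suspension arrays, and with 1 hairpin line and no stated vector control the line and the knockdown cannot be told apart.

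The calls of DDAkt against Suspension could come from degraded RNA, from the slide row or from the construct. The 5' minus 3' difference was -0.199 (interval -0.22 to -0.17). That interval crosses the bound set for intact RNA and does not reach the bound set for degraded RNA, so degradation stays open. In 571 transcripts with a called probe, for which no bound was set, the difference was -0.28. In LY against shPHLPP2, which crosses the same slide rows, these probes moved by a median of 0.0779 in their DDAkt direction (interval 0.065 to 0.089), against a median size of 1.34 in DDAkt. That argues against the row as the whole cause. The construct itself stays open and untested apart from its line.

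The 2 DDAkt arrays lay apart, and unchanged cells in replicate 2 and degraded RNA in replicate 1 were tested as reasons. The 267 probes at least 8-fold down in replicate 1 kept a median of 32.4% of the Suspension level in replicate 2, so unchanged cells could lower the risen probes there by at most 0.57 (interval 0.52 to 0.62). The 345 probes at least 8-fold up in replicate 1 and above background on both DDAkt arrays lay at a median of -1.85 (interval -1.99 to -1.78) in replicate 2 against it. Both sets were chosen by their values in replicate 1, so part of the difference follows from that choice. The intervals resample probes and do not measure the spread between arrays. The test therefore leaves unchanged cells open. The 5' minus 3' difference of replicate 1 against replicate 2 was -0.128 (interval -0.15 to -0.10), which leaves degradation open. No biological explanation was tested.

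Of 32 probes of cancer-testis gene families, 10 were called in shPHLPP2 against Suspension, 8 higher and 2 lower, or 31.3% against 0.328% of all tested probes. The list was defined after the data were seen and narrowed after its members were seen, so a test of it on these data is void and none is given. In DDAkt against Suspension, limma called 12 of the 32 lower and 0 higher. Of all 24405 tested probes it called 2482 lower and 1545 higher there, and 9710 had an unadjusted p under 0.05. Members of the same family are similar in sequence and their probes may share signal, which was not tested, so the probes cannot be taken as independent.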
